A study of Mus musculus with 8 samples.

How the data were processed

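RNA was sequenced from bone marrow-derived macrophages of wild-type C57BL/6 mice and of mice with the Lsd1SA/SA knock-in, which the labels describe as a form of the histone demethylase LSD1 that is defective in phosphorylation. Per the labels, cells at passage 1 were kept without serum for 24 h and were left untreated or given lipopolysaccharide (LPS) for 2 h. The label dose is 1 mg/ml. The titles of the knock-in LPS samples give only the time, and their other labels name LPS. The 4 groups held 2 libraries each, and groups were taken from the sample labels. No label says whether the replicates came from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical.

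The authors deposited one table of 23366 genes by 8 libraries. Its values are a signal made from read counts per gene that the authors divided by a library size scaled with normalization factors, which is the form of TMM-scaled CPM. This was worked out from the values, because each column steps in whole multiples of what 1 read is worth. All values above 0 came out as whole reads within a tolerance of 0.001, which gave library totals of 40379258 to 55595160 reads. Per the submitters' processing notes, TopHat2 2.0.9, bedtools and edgeR were used with the mm9 genome. The counting rule, strand, annotation and filters are not given in the sources used here. Reads of overlapping genes on opposite strands, and of near-identical copies, therefore cannot be assigned with certainty. The library factors worked out from the steps were 1.07 and 1.07 for untreated wild type, 0.878 and 0.866 for wild type with LPS, 1.06 and 1.05 for untreated knock-in, and 1.02 and 1.02 for knock-in with LPS. In the table, 5996 genes were at 0 in every library. The annotation at hand was GENCODE vM21 on GRCm38, another genome build than mm9, so it was used only for which genes neighbour or overlap each other and no coordinates are given.

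Because the values are normalized, the test was limma 3.58.1 in R 4.3.3 on log2(value + 1), 2-sided, with eBayes and a variance trend. Genes with a value of 1 or more in at least 2 libraries were kept, which left 11919. All 8 libraries entered one model of 4 group means with 4 residual degrees of freedom, to which the trend added 19.1 prior degrees of freedom. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, within each of 7 comparisons. A fold change is on the log2(value + 1) scale and understates the change of low genes. Where a group had 0 reads, a lower bound was taken against a floor of 3 reads per library. Where it had 1 to 3 reads, the ratio is given with a 95% counting interval. Floors and intervals cover counting error only, and both take each read as independent. Low counts of the named genes were mostly even numbers, so reads may have been counted in pairs. The bounds would then be too high and the intervals too narrow.

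The comparisons were LPS against untreated in each genotype, knock-in against wild type without and with LPS, the interaction (the LPS effect in the knock-in minus that in wild type), and the genotype and LPS effects averaged over the other factor. The design, the alternatives and the gene lists were fixed before the data were examined. The rule for named genes took Kdm1a, 18 further genes in every comparison, and the 12 largest changes in each direction. A change counted if it passed the threshold, its 2 groups of libraries did not overlap and the higher group mean was at least 5. For the averaged effects this overlap was judged within each level of the other factor, and for the interaction on the ranges of the 2 LPS effects over pairs of libraries. If fewer than 5 passed in a direction, the 5 genes with the smallest unadjusted p were named as well. Up to 4 members were named for a gene list, and predicted genes without a name were not named. Some genes that these rules would name are not reported here. Genes named for other reasons are marked as chosen after their values were seen.

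The 23 gene lists were early inflammatory cytokines and chemokines, NF-kB pathway members and feedback genes, type I interferon response, immediate-early genes, LSD1-CoREST complex and partners, Toll-like receptor signalling components, protein kinase C family, alternative activation, macrophage identity, cell cycle, cholesterol synthesis and uptake, cholesterol efflux and LXR targets, integrated stress response, heat shock, hypoxia and glycolysis, lysosome, and sex-linked markers. The remaining lists were markers of other cells a culture could hold: neutrophils, dendritic cells and antigen presentation, B and T cells, erythroid cells and megakaryocytes, stromal cells and fibroblasts, and mast cells and basophils. The 22 lists with at least 5 tested members went through limma's camera with a preset correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry, which tests whether a list's genes move one way on balance, were alternatives. Genes that responded to LPS in the average of both genotypes by at least 2-fold were tested as sets for the genotype and interaction effects. That average is orthogonal to the interaction in this balanced design.

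Alternatives were the replicate number as a block, each library left out in turn, median-of-ratios and quantile scaling, pseudocounts of 0.25 and 4, no filter and a filter at 5, no or a robust variance trend, only the libraries compared, a 2-fold minimum, an adjusted p under 0.1, and edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on the recovered reads. Leaving out both libraries of the knock-in LPS or the wild-type LPS group was added after the data had been seen. The test was checked on simulated reads for the untreated genotype comparison of 11928 genes. It recovered 83.6% of 67 genes changed 1.5-fold, 97.0% of 67 changed 2-fold and all 66 changed 4-fold, and called 10 unchanged genes. The changed genes were drawn from those with an untreated mean of 1 or more. Noise followed the dispersion trend that edgeR fitted to these libraries. The rates therefore do not cover lower genes or genes that vary more than the trend. No sample column was left out.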

Results

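Transcript levels were measured by RNA-seq in macrophages grown from mouse bone marrow, either wild type or carrying the Lsd1SA/SA knock-in of the histone demethylase LSD1. LPS, a component of the outer membrane of Gram-negative bacteria, was given for 2 h to start an inflammatory response. The title of the series links protein kinase C alpha, LSD1 and NF-kB to control of that response. The comparisons therefore ask what LPS did in each genotype, what the knock-in did, and whether the LPS response differed between genotypes. Each of the 4 groups had 2 libraries of 40379258 to 55595160 reads. Levels are TMM-scaled CPM, given as mean ± SD over the 2 libraries of a group (n = 2). All gene tests are limma with Benjamini-Hochberg adjustment, and all list tests are camera.

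Kdm1a, the gene for LSD1, was read in every library. It stood at 32.5 ± 1.99 in untreated wild type and 33.1 ± 0.795 in untreated knock-in cells. It rose with LPS to 46.5 ± 1.01 in wild type (log2 change 0.51, limma adjusted p = 3.33e-07) and to 39.9 ± 0.801 in the knock-in (0.26, limma adjusted p = 0.00156). A transcript level cannot check the substitution itself, so Kdm1a does not test the genotype labels.

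Sex-linked transcripts set the libraries labelled knock-in LPS apart from the other 6. Xist, the noncoding RNA expressed from the inactive X chromosome, was at 315 to 437 in those 6 libraries and at 0.212 and 0.366 in the knock-in LPS libraries. The Y-linked genes Ddx3y, Eif2s3y, Uty and Kdm5d together had at most 2 reads in any of the 6 libraries, and at least 4993 in each knock-in LPS library. Against untreated knock-in cells, Eif2s3y was at least 554-fold higher, Ddx3y at least 440-fold, Uty at least 355-fold and Kdm5d at least 153-fold. Against wild type with LPS, the bounds were 481-fold for Eif2s3y, 308.0-fold for Uty and 133-fold for Kdm5d. Ddx3y had 2 reads there, and its ratio was 1149 (95% counting interval 318 to 9489, for independent reads). The libraries labelled knock-in LPS thus came from male cells and the other 6 from female cells. They were therefore not from the same animals as the untreated knock-in libraries. Every comparison that uses the knock-in LPS libraries contrasts animals of different sex as well as labels. By list, 4 of these 5 markers were higher and 1 lower in the libraries labelled knock-in LPS than in untreated knock-in cells, also adjusted over the list alone. The median was 4.52 on the fitted scale and 8.47 with genes at 0 reads set to their bound (camera adjusted p = 0.00584, adjusted p = 0.292 with an estimated correlation).

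**Figure D1:**
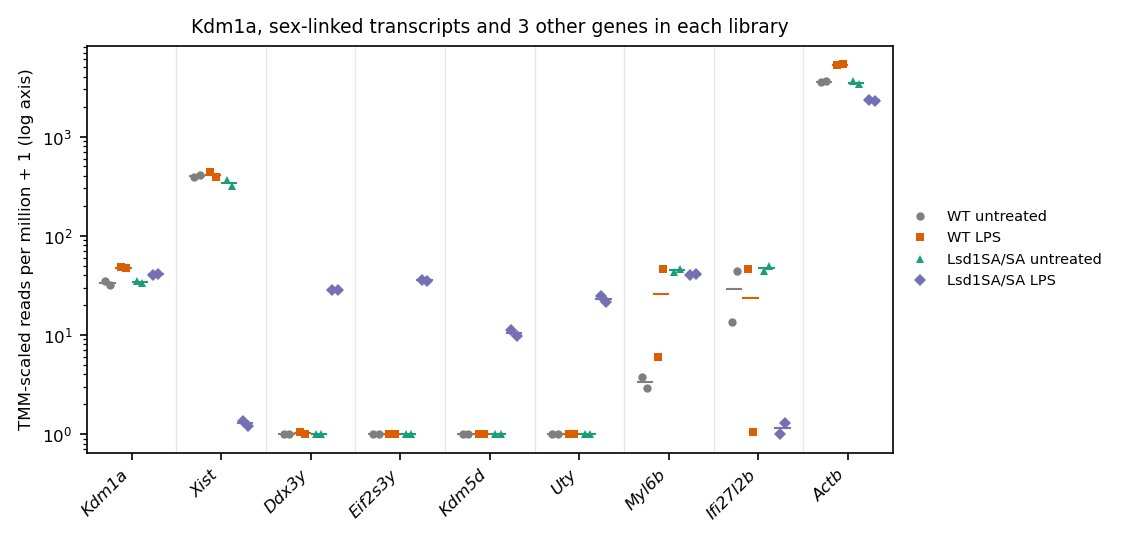
Levels of Kdm1a, sex-linked transcripts and 3 other genes in each of the 8 libraries, in TMM-scaled CPM plus 1 on a log axis. Points are libraries and short lines are group means (n = 2). Xist lies at 315 to 437 in 6 libraries and below 1 in the knock-in LPS libraries, which alone hold at least 4993 reads of the 4 Y-linked genes.

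Libraries of one group were close to each other, with a typical coefficient of variation of 4.73 to 6.08% over well-covered genes. Untreated libraries of different genotype lay at 4.44, 6.16, 6.97 and 8.51%. All but the lowest of these pairs were farther apart than any replicates. All other pairs lay at 16.5 to 30.4%. No pair was within the sampling noise of independent reads, since the lowest mean chi-square per gene was 5.15 where such noise gives 1.

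In wild-type macrophages, LPS raised the genes of the early inflammatory response. Il1b, which encodes the cytokine interleukin 1 beta, went from 1.28 ± 0.00581 to 2202 ± 164. Tnf rose from 27.1 ± 0.392 to 3977 ± 87.3, the chemokine gene Cxcl2 from 2.19 ± 0.0535 to 1918 ± 50.4, and Irg1, whose enzyme makes itaconate, from 6.30 ± 0.275 to 4490.2 ± 163. Fbxo32, a ubiquitin ligase gene, fell from 35.2 ± 1.61 to 1.87 ± 0.661. Both libraries of each group showed these directions, and limma gave 3199 genes higher and 3662 lower of 11919.

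On the log2(value + 1) scale, which places genes from near 0 lower, the 12 largest increases had log2 changes of 6.29 to 9.92. They were Il1b, Irg1, Cxcl2, Cxcl1, Cxcl10, Socs3, Ptgs2, Tnfsf9, Il1a, Tnf, Rnd1 and Marcksl1. Among the largest decreases were Fbxo32, Arrdc3, Hhex, Bmf, Cnr2, Lpar6, Rab40c, Gpr146, Skp2, Ypel2 and Klhl21, at -2.28 to -3.68. Their limma adjusted p was at most 1.07e-14. Ifnb1, the gene for interferon beta, had 0 reads in untreated wild type and was at least 707-fold higher with LPS (44.2 ± 1.70). Il6 (4.26), Il10 (3.95), Il12b (6.22), Ccl2 (4.81), Nos2 (3.11), Nfkbia (4.68), Rela (1.90), Mx1 (2.23) and Actb (0.58) also rose on the log2 scale. Irf7 fell by 0.24, and Prkca, the gene for protein kinase C alpha, did not pass (0.084, limma adjusted p = 0.646).

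Cytokines and chemokines rose as a group in wild type, with 32 of 32 tested members higher and a median log2 change of 4.29 (4.60 with members at 0 reads set to their bound). The camera adjusted p was 2.38e-31. Ccl4 (5.66) and Cxcl10 (8.68) were among the clearest members. All 35 NF-kB pathway members and feedback genes rose (median 3.02, camera adjusted p = 3.50e-37), such as Nfkbiz (5.44) and, of genes that restrain the pathway, Tnfaip3 (5.44) and Nfkbia (4.68). Both calls held with an estimated correlation, each at adjusted p = 0.0484. Of 32 immediate-early genes, which are transcribed within minutes of a stimulus, 28 rose and 2 fell (median 2.20, camera adjusted p = 1.72e-19), with Egr1 at 5.21, Dusp1 at 3.93 and Zfp36 at 3.58. That call had adjusted p = 0.0511 with an estimated correlation. Of 40 type I interferon response genes, 30 rose and 2 fell (median 0.51, camera adjusted p = 1.09e-12, adjusted p = 0.146 with an estimated correlation). Gbp5 (6.28), Rsad2 (4.69) and Oasl1 (3.83) were among those that rose. The counts of these 4 lists were the same adjusted over the list alone.

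Smaller shifts in wild type covered receptors, stress and metabolism. Of 30 Toll-like receptor signalling components, 18 rose and 9 fell (median 0.39, camera adjusted p = 0.00109, adjusted p = 0.163 with an estimated correlation), led by Tlr2 (4.08) and Cd14 (3.41), the LPS co-receptor. Among 12 heat shock genes, 8 rose and 0 fell (camera adjusted p = 0.00405, adjusted p = 0.121 with an estimated correlation, and 0.225 after quantile normalization, in a range over all alternatives of 7.97e-06 to 0.225). Hspa1a (4.44) and Hspa1b (4.77), near-identical copies whose reads cannot be assigned with certainty, led them. Of 18 cholesterol synthesis and uptake genes, 9 rose and 2 fell (camera adjusted p = 0.0345, adjusted p = 0.520 with an estimated correlation, and 0.0617 with the filter at 5, in a range over all alternatives of 0.00109 to 0.520). Of 18 hypoxia and glycolysis genes, 8 rose and 3 fell, with Slc2a1 at 1.84 (median 0.047, camera adjusted p = 0.0476, adjusted p = 0.231 with an estimated correlation). This median was -0.24 after quantile normalization, and the adjusted p was 0.0543 without replicate 2 of untreated wild type and 0.0943 without replicate 2 of wild type with LPS, in a range over all alternatives of 6.69e-05 to 0.988. Adjusted over the list alone, the 4 lists gave the same counts.

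Marker genes of other cells moved in wild type too. Of 17 neutrophil markers, 13 rose (14 adjusted over the list alone), such as Lcn2 (1.79), which macrophages also express after LPS (median 0.61, camera adjusted p = 5.60e-05, adjusted p = 0.0511 with an estimated correlation). Of 11 dendritic cell and antigen presentation markers, 8 rose, such as Cd74 (0.73) and H2-Eb1 (0.86; median 0.65, camera adjusted p = 0.00817, adjusted p = 0.131 with an estimated correlation). Of 8 mast cell and basophil markers, 7 rose, such as Hdc (2.25; median 0.51, camera adjusted p = 0.0130, adjusted p = 0.141 with an estimated correlation). When adjusted over the list alone, the counts of the last pair were the same. Stromal markers had 1 of 12 higher and 2 lower (1 and 0 adjusted over the list alone), and their median (-0.025) and mean (0.055) differed in sign. B and T cell markers had 1 of 6 higher (Klrb1c, 0.47), and of the 4 tested erythroid and megakaryocyte markers 3 were higher (Car2, Pf4 and Itga2b). Both counts were the same adjusted over the list alone. None of the 5 sex-linked markers passed.

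The remaining lists did not pass camera in wild type. The LSD1-CoREST complex and partners had 8 of 19 higher and 6 lower, with Chd4 at 0.71 and Gse1 at -0.74 (adjusted p = 0.727). The protein kinase C family had 1 of 7 higher (Prkcd, 0.58; adjusted p = 0.661). Macrophage identity genes had 7 of 22 higher and 6 lower, with Cebpb at 1.87 and Cebpa at -2.12 (median -0.0050, adjusted p = 0.986, test direction up). After quantile normalization that list was called lower (median -0.24, camera adjusted p = 0.0405). Alternative activation genes had 5 of 13 higher and 2 lower (adjusted p = 0.0512), and cell cycle genes 8 of 30 higher and 2 lower (adjusted p = 0.338), with Mki67 at 2.25. LXR targets had 6 of 11 higher and 3 lower (adjusted p = 0.577), integrated stress response genes 8 of 16 higher and 2 lower (adjusted p = 0.0719), and lysosome genes 2 of 25 higher and 4 lower (1 and 4 adjusted over the list alone; adjusted p = 0.727). The other counts were the same adjusted over the list alone. Of all calls in wild type, 46.6% were higher with the deposited scaling, 35.4% after quantile normalization, 52.0% with median-of-ratios scaling and 52.7% by DESeq2. Without the knock-in LPS libraries, limma called 3164 genes higher and 3594 lower.

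In the libraries labelled knock-in LPS, most inflammatory genes rose far less than in wild type, interferon-response genes were higher and cell cycle genes were lower. Il1b was at 1.47 ± 0.295 untreated and 1.48 ± 0.419 with LPS. Tnf went from 26.6 ± 0.238 to 48.6 ± 0.138 (log2 change 0.85). Ifit3, an interferon-induced gene, went from 84.4 ± 7.72 to 799 ± 6.80, and Top2a, a topoisomerase of dividing cells, from 62.8 ± 4.95 to 13.1 ± 0.240. Xist was -8.05 on the log2 scale between the same libraries, which came from animals of different sex. By limma, 3396 genes were higher and 3368 lower.

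The 12 largest increases held the 4 Y-linked genes and Saa3, an acute-phase gene, which went from 41.7 ± 0.751 to 993 ± 61.1. The others were Ccl8, Ly6a, Plac8, Ms4a4c, Ifit3, Olfml3 and Ly6c1, at log2 changes of 3.16 to 3.76. The 12 largest decreases were Xist, Ifi27l2b, Tsix, Abca9, Mamdc2, Slco2b1, Ephx1, Cdkn1c, Itgax, Stmn1, Atp6v0d2 and Gas7, at -2.47 to -8.05. Among these 24 genes, the limma adjusted p was at most 1.03e-05. That largest value belongs to Ifi27l2b, which varied within groups, and whose adjusted p was 0.0839 with a robust variance trend, in a range over all alternatives of 2.00e-26 to 0.0839. Of the 19 genes followed in every comparison, 11 rose and 3 fell. Among them Ccl2 (1.64), Irf7 (1.34; 574 ± 2.50 to 1456 ± 22.0) and Mx1 (2.94) rose, and Il10 (-0.40), Prkca (-0.47) and Actb (-0.59) fell. The Prkca change shrank to -0.25 without untreated knock-in replicate 1. Its call was lost there and after quantile normalization (limma adjusted p = 0.0600). Cxcl2 (0.21, limma adjusted p = 0.0448) and Nfkbia (0.17, 0.0155) passed narrowly. Without knock-in LPS replicate 2, their adjusted p was 0.361 and 0.0948, and without untreated knock-in replicate 1 it was 0.0956 and 0.151, in ranges over all alternatives of 0.00285 to 0.361 and 0.00317 to 0.151. Ifnb1 had 2 reads in untreated knock-in cells and 56 with LPS, a ratio of 25.2 (95% counting interval 6.66 to 213, for independent reads).

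All 40 type I interferon response genes rose in this comparison, by a median of 1.64 (camera adjusted p = 1.11e-38, adjusted p = 0.0686 with an estimated correlation). Isg15 (3.07), Rsad2 (2.77) and Oas3 (2.24) were among them. All 30 cell cycle genes fell, with a median of -1.50, and this call held with an estimated correlation (camera adjusted p = 9.94e-23, adjusted p = 0.0192 with an estimated correlation). Mki67 (-2.06), Rrm2 (-2.17) and Mcm5 (-1.63) were examples. Of 18 cholesterol synthesis and uptake genes, 15 fell and 0 rose, such as Sqle (-1.41; median -0.60, camera adjusted p = 3.12e-07, adjusted p = 0.177 with an estimated correlation). Of 11 LXR targets, 7 fell and 2 rose, with Abca1 at -1.02 (camera adjusted p = 0.0389, adjusted p = 0.191 with an estimated correlation, 0.0923 with no filter and 0.0708 with the filter at 5, in a range over all alternatives of 3.65e-05 to 0.191). These libraries also differed in Xist and the Y-linked transcripts. The 4 lists gave the same counts adjusted over the list alone.

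Of 32 cytokines and chemokines, 16 rose and 4 fell, by a median of 0.22, with Ccl7 (2.45), Ccl2 (1.64) and Ccl5 (1.51) among those higher (camera adjusted p = 0.00186, adjusted p = 0.292 with an estimated correlation). Of 35 NF-kB genes, 25 rose and 6 fell (7 adjusted over the list alone; median 0.40, camera adjusted p = 2.64e-05, adjusted p = 0.191 with an estimated correlation), with Gadd45b at 1.60. Toll-like receptor components had 16 of 30 higher and 3 lower, with Tlr3 at 0.96, Tlr9 at 0.90 and Cd14 at -0.9993 (camera adjusted p = 0.0110, adjusted p = 0.280 with an estimated correlation). Integrated stress response genes had 11 of 16 higher and 3 lower, with Trib3 at 0.94 (camera adjusted p = 0.00783, adjusted p = 0.458 with an estimated correlation). Immediate-early genes were split, with 11 of 32 higher and 10 lower (median 0.022, mean -0.017, camera adjusted p = 0.464). Egr2 (-2.02) and Myc (-1.76) were lower there and Dusp1 (1.05) higher. Adjusted over the list alone, the other counts were the same.

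Markers of other cells moved apart in the libraries labelled knock-in LPS. Stromal markers rose in 11 of 12, by a median of 0.90 (camera adjusted p = 1.85e-04, adjusted p = 0.0686 with an estimated correlation). The collagen gene Col1a1 went from 4.83 ± 0.381 to 18.7 ± 2.10. Neutrophil markers rose in 13 of 17, with Mmp8 at 1.47 (median 0.38, camera adjusted p = 1.96e-04, adjusted p = 0.0686 with an estimated correlation). Mast cell and basophil markers rose in 7 of 8, with Prss34 at 1.54 (median 0.76, camera adjusted p = 0.00344, adjusted p = 0.127 with an estimated correlation). Dendritic cell and antigen presentation markers had 7 of 11 lower and 1 higher, with Itgax at -2.76 (median -0.49, camera adjusted p = 0.0290, adjusted p = 0.191 with an estimated correlation, and 0.122 with the filter at 5, in a range over all alternatives of 1.14e-04 to 0.191). Macrophage identity genes did not pass, with 7 of 22 higher and 7 lower (median -0.083, mean 0.020). Fcgr1 (1.66) rose and Cd36 (-0.83) fell. Adjusted over the list alone, these 5 lists gave the same counts. Of 6 B and T cell markers, 3 were lower (4 adjusted over the list alone) and 0 higher, such as Cd79b (-1.16; median -0.37, camera adjusted p = 0.102). Of the 4 tested erythroid and megakaryocyte markers, 2 were lower (Epor and Pf4), also over the list alone.

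Between the untreated genotypes, only Myl6b passed limma. Tnf stood at 27.1 ± 0.392 in wild type and 26.6 ± 0.238 in the knock-in, and Irf7 at 549 ± 11.7 and 574 ± 2.50. Myl6b, a myosin light chain gene, was at 2.32 ± 0.572 in wild type and 43.7 ± 2.31 in the knock-in (log2 change 3.76, SE 0.44, limma adjusted p = 1.83e-04). The wild-type LPS libraries held 5.00 and 45.1, so Myl6b also varied within a genotype. Over the 23 alternatives that gave an adjusted p, it ranged from 1.30e-21 to 0.445, and the call was lost with no filter (0.432), no variance trend (0.445) and a robust trend (0.263).

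No gene passed limma as lower in untreated knock-in cells. In either direction, 1617 of 11919 genes had an unadjusted limma p under 0.05, a larger share than the 0.05 that chance gives on average. The quasi-likelihood test of edgeR called 1 higher and 0 lower, and DESeq2 called 42 higher and 37 lower. The independent filtering of DESeq2 left 3429 genes with an adjusted p in this comparison. Myl6b was not among them (unadjusted p = 1.58e-05), nor were 9 other named genes, Kdm1a included. The limma count depends on 1 library and rose without replicate 1 of untreated wild type. That fit leaves 1 untreated wild-type library, which has no spread of its own. The library left, replicate 2, lay farther from the untreated knock-in libraries than replicate 1 did. The typical coefficient of variation was 6.97 and 8.51% for replicate 2, and 4.44 and 6.16% for replicate 1. Closest to passing among higher genes were Tst (0.67, limma adjusted p = 0.0706), Myl6 (0.28), Crlf2 (0.27), Rpl37 (0.23) and Atf5 (0.26). Among lower genes they were Top1 (-0.30, limma adjusted p = 0.0627), Cmah (-0.73), Tank (-0.30), Atrx (-0.32) and Tpr (-0.25). Of the tested genes, 99.9% had a 95% interval within 1 log2 unit of 0, and 98.2% within 1.5-fold. Both shares are on the log2(value + 1) scale, where genes near 0 barely move with a 2-fold change. The interval was -0.13 to 0.073 for Tnf, -0.11 to 0.34 for Il1b and -0.11 to 0.16 for Kdm1a. For Nfkbia it was 0.020 to 0.25, above 0, and the limma adjusted p was 0.293.

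No list member passed limma over all genes in untreated cells. With adjustment over the list alone, 5 interferon-response genes passed, Irf1 (0.19) and Bst2 (0.17) as higher and Ifi44 (-0.30), Parp14 (-0.19) and Ddx58 (-0.18) as lower. The cell cycle genes Cenpe (-0.36) and Mki67 (-0.27), Mrc1 (-0.20), Maf (-0.16) and Xist (-0.24) passed as lower, and Trem2 (0.19), Atf5 (0.26) and Col1a1 (0.44) as higher, each within its own list; all of these were named after their values were seen. Camera called the Toll-like receptor components lower (median -0.049) and the stromal markers higher (median 0.17) in untreated knock-in cells, both at adjusted p = 0.0463 and at adjusted p = 0.697 with an estimated correlation. Each call was lost without 1 library in several cases, with adjusted p in ranges over all alternatives of 0.0202 to 0.697 and 0.00383 to 0.697. The stromal median shrank to 0.086 without replicate 2 of untreated wild type and to 0.10 without replicate 1 of untreated knock-in cells. That of the Toll-like receptor components was -0.034 without replicate 1 of untreated wild type.

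With LPS, the libraries labelled knock-in held far less inflammatory transcript than wild type and more of many interferon-response genes. Tnf was at 3977 ± 87.3 in wild type and 48.6 ± 0.138 in the knock-in, and Cxcl2 at 1918 ± 50.4 and 2.46 ± 0.314. Ptgs2, the inducible cyclooxygenase gene, was at 453 ± 28.3 and 1.19 ± 0.0619. Ly6a went the other way, at 42.0 ± 1.58 and 750.0 ± 13.7. Xist (-8.32) and the Y-linked genes differed between the same libraries. By limma, 4593 genes were higher and 4389 lower in the libraries labelled knock-in LPS.

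Besides the Y-linked Eif2s3y, Ddx3y and Uty, the 12 largest increases were Lrrc14b, Ly6a, Ccdc127, Fbxo32, Ccl8, Ms4a4c, Arrdc3, Saa3 and Olfml3, at log2 differences of 3.53 to 4.39. Lrrc14b (19.0 ± 0.710 and 417 ± 12.5) and Ccdc127 (16.8 ± 0.129 and 294 ± 10.4) overlap on opposite strands, and without strand their reads cannot be assigned to either gene. The 12 largest decreases were Il1b, Cxcl2, Cxcl1, Xist, Cxcl10, Ptgs2, Socs3, Il1a, Tnfsf9, Tnf, Il12b and Maff, at -6.26 to -9.80. The limma adjusted p of these 24 was at most 7.28e-19. Of the 19 genes followed throughout, 17 were lower and 2, Irf7 (1.65) and Mx1 (0.67), higher. Kdm1a was -0.22 (limma adjusted p = 0.00406).

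Cytokines and chemokines were lower in 31 of 32 (median -3.76, camera adjusted p = 1.19e-18, adjusted p = 0.0833 with an estimated correlation). NF-kB genes were lower in 35 of 35 (median -2.34, camera adjusted p = 7.95e-23, adjusted p = 0.0704 with an estimated correlation). Immediate-early genes were lower in 29 of 32 and higher in 2 (median -2.32, camera adjusted p = 5.00e-12, adjusted p = 0.107 with an estimated correlation), with Egr1 at -6.02. Cell cycle genes were lower in 30 of 30 (median -1.77, camera adjusted p = 2.19e-13, adjusted p = 0.0556 with an estimated correlation), with Mki67 at -4.58. Cholesterol synthesis and uptake genes were lower in 15 of 18 and higher in 1 (median -1.17, camera adjusted p = 5.92e-06, adjusted p = 0.188 with an estimated correlation). Of 40 interferon-response genes, 24 were higher and 15 lower (median 0.84, camera adjusted p = 0.0471, adjusted p = 0.550 with an estimated correlation). That call was also lost with the replicate number as a block (camera adjusted p = 0.0550) and with a pseudocount of 4 (0.0518). Oas3 (2.27) and Stat2 (1.95) were higher, and Irf1 (-3.06) and Gbp5 (-4.56) lower. Each of these 6 lists gave the same counts adjusted over the list alone.

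Stromal markers were higher in 10 of 12 and lower in 2 (median 1.13, camera adjusted p = 0.00959, adjusted p = 0.132 with an estimated correlation), with Col1a1 at 2.39. Dendritic cell and antigen presentation markers were lower in 9 of 11 and higher in 2 (median -1.02, camera adjusted p = 0.00959, adjusted p = 0.132 with an estimated correlation). Toll-like receptor components were lower in 16 of 30 (17 adjusted over the list alone) and higher in 8, with Cd14 at -4.37 (camera adjusted p = 0.0468, adjusted p = 0.374 with an estimated correlation, and 0.0628 without knock-in LPS replicate 2, in a range over all alternatives of 2.12e-05 to 0.374). Heat shock genes were lower in 8 of 12 and higher in 3 (camera adjusted p = 0.0468, adjusted p = 0.188 with an estimated correlation, and 0.303 after quantile normalization, in a range over all alternatives of 5.44e-06 to 0.303). With the filter at 5, camera called 7 lists in place of 11: the interferon, Toll-like receptor, dendritic cell and sex-linked lists then had adjusted p = 0.056 each. Adjusted over the list alone, the counts not given were the same.

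By the interaction, the difference between LPS and untreated libraries was smaller in the knock-in for most inflammatory genes. In the knock-in that difference also holds the change of animals, so the interaction does not isolate the LPS response of the genotypes. The value of the interaction is the log2 LPS effect in the knock-in minus that in wild type. It was -9.92 for Il1b, -6.30 for Tnf, -4.52 for Nfkbia and 3.95 for Ly6a. By limma, 3794 genes had a higher and 3794 a lower LPS effect in the knock-in. The share higher was 56.9% after quantile normalization and 47.7% with median-of-ratios scaling. Of the 153 genes that rose at least 8-fold with LPS in wild type, all 153 had a lower effect in the knock-in, 1 rose at least 8-fold there, and the median log2 change was 3.998 in wild type and 0.33 in the knock-in. These genes were chosen on wild type, which favours a smaller knock-in value.

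Genes chosen without that bias gave the same direction. The 425 genes that rose at least 2-fold in the LPS effect averaged over genotypes had a median log2 LPS effect of 2.37 in wild type and 0.55 in the knock-in. Their median interaction was -1.93, with 337 lower and 70 higher (camera adjusted p = 2.28e-34, adjusted p = 0.00811 with an estimated correlation). The 107 genes that fell at least 2-fold had medians of -1.10 and -1.30 and a median interaction of -0.12 (camera adjusted p = 0.834). In untreated cells the 425 genes had a median genotype difference of -0.0045 (camera adjusted p = 0.962).

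Of 3199 genes higher with LPS in wild type, 1174 were also higher in the knock-in, 845 were lower and 1180 did not pass. Independent lists of these sizes would share 911. Of 3662 genes lower in wild type, 920 were lower in the knock-in and 1028 higher, where independent lists would share 1035. Across all tested genes, which are not independent replicates, the LPS effects of the genotypes had a Pearson r of 0.12 and a slope of 0.080. By list, the interaction was lower in 31 of 32 cytokines and chemokines, 35 of 35 NF-kB genes, 27 of 32 immediate-early genes and 30 of 30 cell cycle genes, and these counts were the same adjusted over the list alone. With an estimated correlation, the NF-kB (adjusted p = 0.0485) and cell cycle (adjusted p = 0.0482) calls held. The cytokine (adjusted p = 0.0602) and immediate-early (adjusted p = 0.0823) calls did not. The other animals of the knock-in LPS libraries enter this contrast for all genes, not only for the Y-linked ones.

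**Figure D2:**
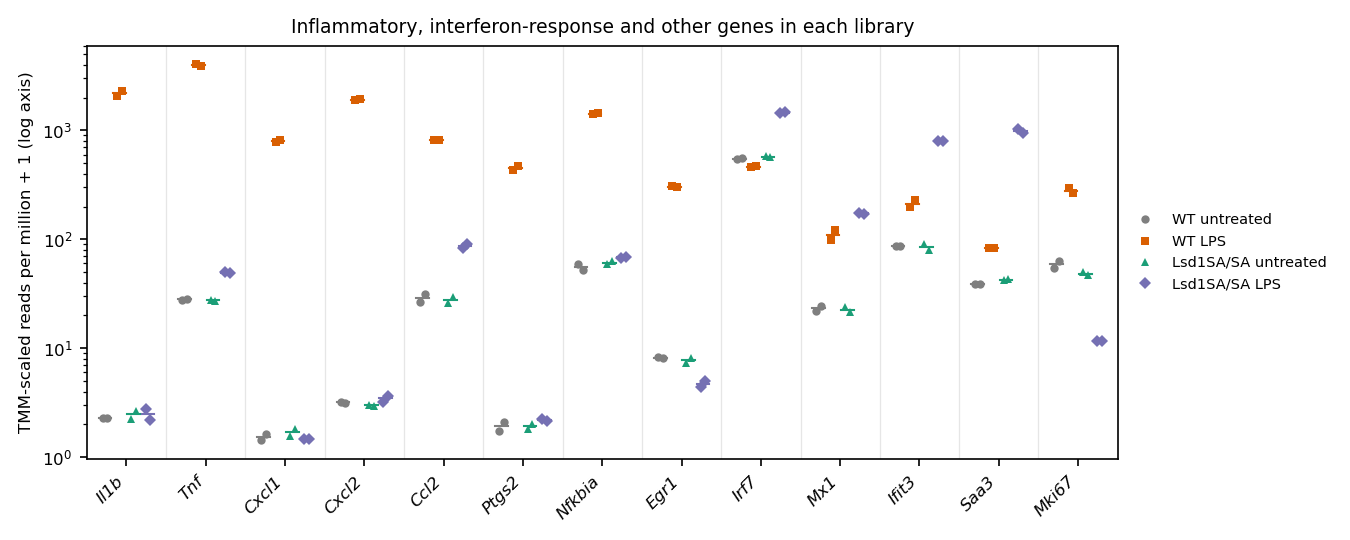
Levels of inflammatory, interferon-response and other genes in each library, in TMM-scaled CPM plus 1 on a log axis; points are libraries and short lines are group means (n = 2). Il1b, Tnf, Cxcl2 and Nfkbia lie far above the other groups in wild type with LPS, and Irf7, Ifit3 and Saa3 in the libraries labelled knock-in LPS.

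**Figure D3:**
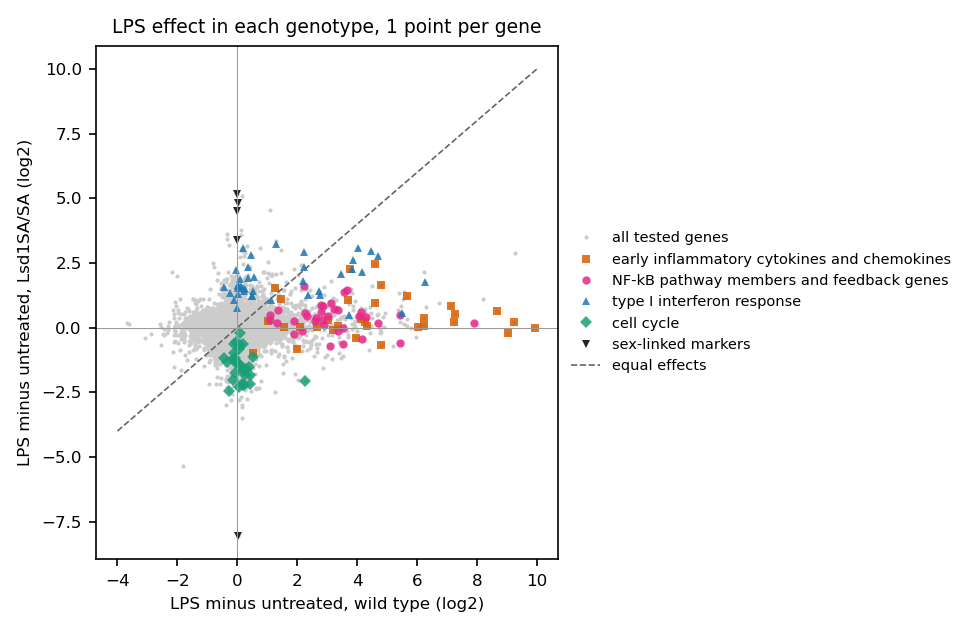
The log2 LPS effect in the knock-in against that in wild type, 1 point per tested gene, with 5 gene lists coloured and a dashed line for equal effects. Cytokine and NF-kB genes stretch along the wild-type axis, and cell cycle genes lie below 0 on the knock-in axis.

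Averaged over treatment, the knock-in libraries had higher Lrrc14b, Ly6a, Ccdc127, Saa3, Rhov, Ly6c2, Cnr2, S1pr2, Il12rb1, Cebpa, Col1a1 and Rab40c, at log2 differences of 1.38 to 2.23. They had lower Cxcl2, Xist, Socs3, Gem, Tnf, Nfkbiz, Ccl22, Olr1, Mki67, Il10, Cd83 and Pcdh7, at -2.30 to -4.61. Xist was only -0.24 between the untreated genotypes, so its average reflects the male cells of the knock-in LPS libraries. The other animals of those libraries enter every average here. Limma called 4115 genes higher and 3959 lower, and the adjusted p of the named 24 was at most 1.94e-12. Of the comparisons averaged here, limma called 1 gene between untreated libraries and 8982 between LPS libraries. Cytokines and chemokines were lower in 31 of 32 and cell cycle genes in 30 of 30 (camera adjusted p = 1.38e-20 and 6.49e-14), at adjusted p = 0.0698 and 0.0515 with an estimated correlation. These counts were unchanged when adjusted over the list alone.

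Averaged over genotype, LPS raised Irg1, Cxcl2, Cxcl10, Socs3, Clec4e, Ptgs2, Gbp5, Tnf, Tnfsf9, Rnd1, Rsad2 and Il1a, at log2 changes of 3.73 to 6.07. The average was lower for Ier5l, Sesn1, Hhex, Slco2b1, Lpar6, Bmf, Rnf144b, Gpr183, Cdkn1c, Npas4, Adam19 and Dusp6, at -1.40 to -1.81. Some of these averages came mostly from a single genotype. Slco2b1 was -0.39 in wild type and -2.99 in the knock-in, Cdkn1c -0.20 and -2.79, and Ptgs2 7.89 and 0.19. The knock-in LPS libraries, from animals of another sex, enter every average. Sesn1 fell in both genotypes, from 131 ± 6.62 to 34.6 ± 3.76 in wild type and from 131 ± 1.85 to 41.1 ± 3.26 in the knock-in. Limma called 3418 genes higher and 4071 lower. Interferon-response genes rose in 40 of 40 and NF-kB genes in 35 of 35, and both calls held with an estimated correlation (adjusted p = 0.0449 and 0.0326). Both counts were the same adjusted over the list alone. Lysosome genes had 9 of 25 higher and 7 lower, with a median of 0.0084 that was -0.17 after quantile normalization, where camera called them lower (adjusted p = 0.00462).

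**Figure D4:**
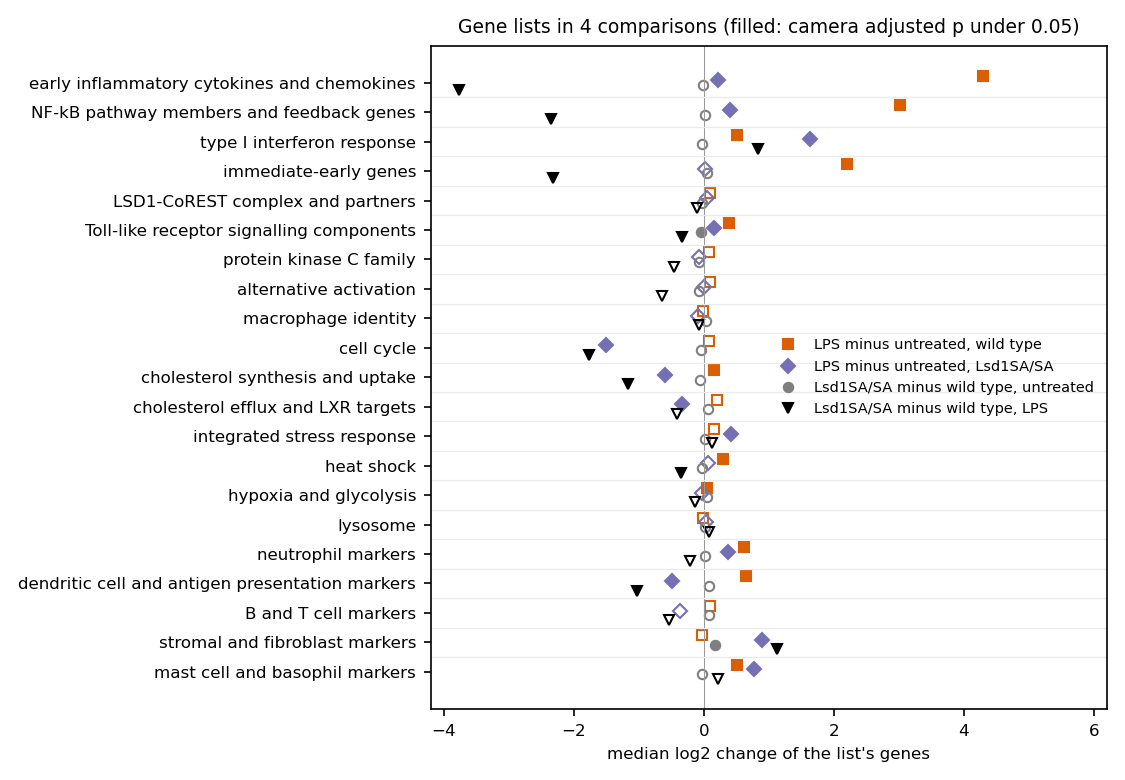
Median log2 change of the tested gene lists, without the sex-linked markers, in 4 comparisons; symbols are comparisons, filled where the camera adjusted p is under 0.05 at the preset correlation. Cytokine, NF-kB and immediate-early lists lie at 2.20 to 4.29 for LPS in wild type and at -2.32 to -3.76 for the knock-in against wild type with LPS.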

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

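The interaction tests in this part were planned, and the tests of explanations and the counts of splits were chosen after the results had been seen. Each result here stands because the LPS effect differed between the groups labelled wild type and knock-in by limma's interaction term. In the knock-in, that effect also holds the change of animals. That term was higher for 3794 genes and lower for 3794. Genes that rose with LPS in the average of both genotypes had a median interaction of -1.93. By list, the median interaction was -3.73 for cytokines and chemokines, -2.34 for NF-kB genes, -2.35 for immediate-early genes, -1.67 for cell cycle genes, -1.17 for cholesterol synthesis and uptake, -0.84 for dendritic cell and antigen presentation markers and -0.32 for heat shock genes. It was 0.83 for interferon-response genes, 0.90 for stromal markers and 4.52 for sex-linked markers. Camera called these 10 lists, of which 2 held with an estimated correlation. After quantile normalization the heat shock call was lost (adjusted p = 0.259), and with a pseudocount of 0.25 the sex-linked call was (adjusted p = 0.0574), in ranges over all alternatives of 2.97e-05 to 0.259 and 4.39e-06 to 0.367.

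Of the genes named for LPS in wild type, for the interaction or in every comparison, the interaction was lower for Il1b (-9.92), Cxcl1 (-9.23), Cxcl2 (-9.02), Cxcl10 (-8.03), Ptgs2 (-7.69), Socs3 (-7.06), Il1a (-6.99), Tnfsf9 (-6.73), Irg1 (-6.39), Maff (-6.33), Tnf (-6.30), Il12b (-6.18), Rnd1 (-5.78) and Marcksl1 (-5.51). Smaller values were those of Ifnb1 (-4.93), Nfkbia (-4.52), Il10 (-4.35), Il6 (-4.06), Ccl2 (-3.17), Nos2 (-2.18), Rela (-1.66), Actb (-1.17), Prkca (-0.56) and Kdm1a (-0.25). The Kdm1a call was lost after quantile normalization and without 1 library in 4 cases, for example at adjusted p = 0.0934 without replicate 2 of untreated wild type, in a range over all alternatives of 0.00749 to 0.0934. The Prkca call was lost with no filter (limma adjusted p = 0.0814), by DESeq2 (adjusted p = 0.0523) and without 1 library in 4 cases. Without replicate 1 of untreated knock-in cells, the Prkca interaction shrank to -0.33.

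Genes lower in both libraries labelled knock-in LPS than in the other 6 were Xist (-8.08), Gas7 (-3.72), Tsix (-3.65), Abca9 (-3.20), Mamdc2 (-3.15), Itgax (-3.06), Ephx1 (-2.83), Stmn1 (-2.79), Slco2b1 (-2.60), Cdkn1c (-2.59) and Atp6v0d2 (-2.42). The interaction was also lower for Ifi27l2b (-3.55), but it was at 45.4 and 0.0452 in the wild-type LPS libraries. Its size therefore depends on which of these libraries is used. It was higher for the Y-linked Eif2s3y (5.15), Ddx3y (4.79), Uty (4.52) and Kdm5d (3.39), where the fitted size depends on the pseudocount, and edgeR did not call Eif2s3y, Ddx3y or Uty. It was also higher for Lrrc14b (4.32), Ccdc127 (3.999), Ly6a (3.95), Ms4a4c (3.76), Ccl8 (3.65), Olfml3 (3.46), Saa3 (3.44), Plac8 (3.44), Ly6c1 (2.83), Ifit3 (1.95), Irf7 (1.58) and Mx1 (0.71). Genes that fell in wild type had positive values, namely Fbxo32 (3.84), Arrdc3 (3.74), Cnr2 (2.71), Hhex (2.68), Bmf (2.64), Rab40c (2.56), Klhl21 (2.51), Gpr146 (2.21), Skp2 (2.16), Ypel2 (2.12) and Lpar6 (1.87).

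The smaller induction of inflammatory genes in the libraries labelled knock-in LPS was weighed against technical explanations. Library scaling is argued against, since the median interaction of the cytokine list was at most -3.50 over the deposited and 2 other scalings. A swap of treatment labels within the knock-in is argued against, since the untreated knock-in libraries had that list at a median of -0.015 from untreated wild type and so held no induction. A sample that received no LPS or came from outside the series cannot be told apart from an effect of the knock-in, because the 153 genes raised at least 8-fold in wild type had a median of 0.33 in the knock-in. Of these 153, limma called 86 higher and 19 lower there, which counts against no response at all only if the samples are otherwise alike. The knock-in LPS libraries did come from other animals than the untreated knock-in libraries. Xist changed by -8.05, and they alone held at least 4993 reads of the Y-linked genes. Animals and LPS label cannot be separated in the knock-in, so what other animals or another culture did to these genes stays open. A weaker LPS response caused by the knock-in, which the design names, may account for the pattern and was not tested apart from these.

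The closeness of the untreated genotypes was weighed in the same way. One library deposited under both genotypes is argued against, since the lowest mean chi-square per gene between them was 5.15. Sampling noise of independent reads gives 1. Too little precision is argued against for 2-fold effects only in genes well above the added 1. On the log2(value + 1) scale, 99.9% of genes had a 95% interval within 1 log2 unit of 0. Genes near 0 in untreated cells barely move on that scale with a 2-fold change, so they are not covered. By DESeq2, the SE of the log2 difference was 0.936 for Il12b and 1.77 for Ifnb1. Untreated libraries taken from the same cells cannot be told apart from a knock-in with little or no effect in untreated cells. The coefficients of variation across genotypes were 4.44, 6.16, 6.97 and 8.51%, against 4.73 to 6.08% for replicates. The lowest lay below the replicates and the others above them. What the replicates are is not known, so their spread cannot decide this. Myl6b differed between the untreated genotypes, but also within wild type with LPS.

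The higher interferon-response and lower cell cycle genes in the libraries labelled knock-in LPS were the last pattern weighed. Library scaling is argued against for the difference between knock-in LPS and untreated knock-in libraries. There the interferon list median stayed at 1.64 or more and the cell cycle median at -1.46 or less over the 3 scalings. The interaction was not weighed by this test. Its median ranged over all alternatives from 0.79 to 1.08 for the interferon list and from -1.85 to -1.23 for the cell cycle list. A lower share of macrophages as the source of the cell cycle change is argued against, since the macrophage identity median lay 1.42 above the cell cycle median, more than the SD of its members (0.508), a test that replaced an earlier one on stromal and dendritic cell markers. RNA of other cell types as a source of the interferon change cannot be told apart from a change in macrophages, since the stromal median rose by 0.90 while dendritic cell markers, which macrophages share, fell. The other animals of the knock-in LPS libraries (Xist -8.05), or another culture, cannot be separated from the LPS label as above. A biological effect of the knock-in may account for the pattern but was not tested apart from them.

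For the effects averaged over 4 libraries against 4, the libraries were split in all 34 ways that can be fitted beside the other factor, the real one included; an earlier count had used only the splits within the other factor. For genotype, 1 split gave as many genes as the real 8074, which was the real one, and the highest other gave 7709. The 5 highest others, at 7403 to 7709, all set the LPS libraries of the genotypes apart, so the count points to the distance between the LPS groups and chance is not excluded on it. For LPS, 2 splits gave at least the real 7489. The other gave 7588 and set untreated wild type with knock-in LPS, which is the interaction, so this count does not exclude chance.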

How the results depend on the processing

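All alternatives were planned except leaving out both LPS libraries of a genotype and the recomputed LPS-responsive sets other than with a 4-fold minimum or an estimated correlation, which were chosen after the data had been seen. Named genes were recomputed 5674 times. In 5530 cases they kept their side of the threshold, in 70 a call was lost and in 74 one was gained. No gene changed direction where either fit called it. Direction was not compared where neither fit called the gene, and it did change there, as for untreated Kdm1a (-0.033 to 0.088). Gene lists were recomputed 2660 times, with 2452 kept, 124 calls lost, 81 gained and 3 reversed. The cause of a lost or reversed call was not tested unless stated. Limits are 2 libraries per group, with 4 residual degrees of freedom, and the animals of other sex behind the knock-in LPS libraries, which enter each comparison that uses them. At 40379258 to 55595160 reads per library, changes from 0 reads are known only as bounds.

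The reversed lists were macrophage identity (median -0.24) and hypoxia and glycolysis (-0.24) for LPS in wild type, and lysosome (-0.17) for LPS averaged, all under quantile normalization, which moved the median LPS effect of all genes in wild type by -0.055.

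In numbers of genes, comparisons with LPS changed more: LPS in wild type kept 5261 of 6861 calls under quantile normalization. Relative to its count of 1 gene, the untreated genotype comparison changed most. Genes higher and lower numbered 4 and 14 with a robust variance trend, 5 and 7 with only the libraries compared, 6 and 14 at an adjusted p under 0.1, 42 and 37 by DESeq2, and 4 and 9 without the wild-type LPS libraries. Genes higher numbered 0 with no filter and 0 with no variance trend, where Myl6b was lost. Genes lower numbered 1 with a pseudocount of 4 and 1 without the knock-in LPS libraries. With each library left out, genes higher ranged from 1 to 263 and lower from 0 to 220, with the highest of both without replicate 1 of untreated wild type. In that fit the lone library is assumed to vary like the other groups. Gene lists called ranged from 0 to 4 with each library left out, and numbered 0 under quantile normalization, a pseudocount of 4, no filter, without either pair of LPS libraries, with an estimated correlation and with fry. The 107 genes that fell at least 2-fold with LPS in the average of both genotypes had an untreated median of -0.041, called lower at the preset correlation. That call was lost with an estimated correlation (-0.041), median-of-ratios scaling (-0.044), a pseudocount of 4 (-0.027) and the filter at 5 (-0.040), and medians ranged from -0.082 to -0.022 with each library left out.

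A 2-fold minimum lowered the counts by its construction, to 771 higher and 468 lower for LPS in wild type, 307 and 410 for LPS in the knock-in, 863 and 1130 for genotype with LPS, 858 and 1106 for the interaction, 107 and 368 for genotype averaged, and 425 and 107 for LPS averaged. With an estimated correlation, camera called 2 lists for LPS in wild type, 1 for LPS in the knock-in, 0 for genotype with LPS, 2 for the interaction, 0 for genotype averaged and 6 for LPS averaged. Fry, which asks another question, called 19 lists for LPS in wild type, 21 for genotype with LPS, 21 for the interaction, 19 for genotype averaged and 20 for LPS averaged. For genotype with LPS, camera called 7 lists with the filter at 5.

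The deviations of same-numbered libraries had correlations of -0.084 to 0.089, so no strong shared effect of the replicate number was seen. Whether same-numbered libraries were paired cannot be told from this, and no label gives it. With the replicate number as a block, limma called 3196 higher and 3661 lower for LPS in wild type and 3376 and 3360 in the knock-in, and camera called 7 lists for genotype with LPS in place of 11. The set of genes at least 4-fold lower in the averaged LPS effect was not run, because it held 2 genes, under the minimum of 5. Leaving out both knock-in LPS libraries could not be run for comparisons made of them.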

Other observations

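The patterns in this part were chosen after the data had been seen, and limma's tests of them were planned for all genes. Between the genotypes, interferon-response genes did not move as a block, with an interaction that was higher for 24 of 40 and lower for 14. Irf1, an interferon regulatory factor, stood at 1034 ± 27.2 in wild type with LPS and 123 ± 2.29 in the libraries labelled knock-in LPS (interaction -3.25, limma adjusted p = 4.88e-22). Gbp5 was at 450.3 ± 22.7 and 18.1 ± 0.414 (interaction -4.54) and Rsad2 at 1804 ± 129 and 436 ± 9.83 (-1.91). Usp18 went the other way, at 28.4 ± 1.87 and 195 ± 0.0944 (2.88), and so did Oas3, at 195 ± 1.60 and 944 ± 16.3 (2.27). Oas3 did not pass for LPS in wild type (limma adjusted p = 0.576). The activating Fc receptor gene Fcgr1, which interferon gamma induces, was at 287 ± 1.77 in untreated knock-in cells and 913 ± 20.7 in the libraries labelled knock-in LPS, against 277 ± 11.5 and 257 ± 3.23 in wild type. The limma interaction of Fcgr1 was 1.77 (adjusted p = 2.47e-17).

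Other genes differed in direction or size between the genotypes. Cebpa went from 219.8 ± 24.3 to 49.6 ± 3.45 in wild type and from 249 ± 15.6 to 320.1 ± 34.3 in the knock-in (interaction 2.48, limma adjusted p = 1.80e-16). Mki67, a marker of dividing cells, rose in wild type from 57.8 ± 5.73 to 279 ± 22.2, while the cell cycle list as a whole did not pass there, and fell in the knock-in from 47.5 ± 2.27 to 10.6 ± 0.122 (interaction -4.31). Slc7a11, the cystine transporter gene, rose from 8.37 ± 0.580 to 91.0 ± 3.45 in wild type and stood at 9.58 ± 0.387 and 8.66 ± 0.115 in the knock-in (interaction -3.43). The overlapping genes Lrrc14b and Ccdc127 moved together, and Lrrc14b fell from 89.4 ± 0.380 to 19.0 ± 0.710 in wild type and rose from 93.8 to 417 ± 12.5 in the knock-in.

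Some genes varied within groups far more than most. In the order untreated wild type, wild type with LPS, untreated knock-in and knock-in with LPS, the 8 libraries held 2.73, 1.92, 5.00, 45.1, 42.1, 45.4, 38.9 and 40.4 for Myl6b. Ifi27l2b held 12.5, 43.5, 45.4, 0.0452, 43.3, 48.2, 0 and 0.282. Lars2 held 68.1, 62.7, 94.2, 290.5, 82.9, 73.4, 104 and 443. Myl6, the neighbour of Myl6b on the same strand, held 393, 377, 448, 513, 457, 481, 427 and 467. No test of why these genes varied was made.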
